A study of Caenorhabditis elegans with 2 samples.

How the data were processed

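ChIP-seq of UNC-98::GFP from starved L1 larvae of strain OP85 was measured in 2 biological replicates, numbered as in the labels. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an anti-GFP antibody. Per the files that describe the deposited lists, reads of each replicate were aligned to the genome build ce11 and the lists were derived from filtered alignments and a control file; the aligner, its version and the peak caller are not given in the sources used here. The 8 deposited lists were complete, in that the checksum stated for each one matched. Regions were called per replicate and on both replicates together. For each replicate and for the series there is a ranked list of candidate regions (103403 for replicate 1, 106737 for replicate 2, and 131481 and 131786 for the series) and a thresholded list. The series has a thresholded list made from agreement between the replicates (conservative, 728 regions) and a second one (790 regions).

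The deposited signal values are the score the authors' software gave each region, at a scale not stated, and were used to describe and rank regions within a list. The ranked lists also give the deposited −log10 of the global IDR, capped at 5. The lowest −log10 IDR of any region in the thresholded lists lay just above 2, so the threshold in the files is an IDR of 0.01. The analysis had been planned for an IDR threshold of 0.05 with 0.01 as the stricter setting; since 0.01 was already in force, that setting moves nothing and an IDR of 0.001 was added after the data were examined. No read counts are used, so the depth per sample is unknown and gives no interval; the 95% Wilson intervals printed cover the number of regions only. With 1 group of 2 replicates no test between groups of samples was possible, and the p-values compare regions or genes within these 2 libraries.

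The main list was the conservative one. Positions were taken at the summit the files give. Genes came from the Ensembl release 115 annotation of the same build, and sequence from the RefSeq copy of it, on the 6 nuclear chromosomes. A promoter window ran from 1000 bp upstream to 500 bp downstream of the 5′ end of any protein-coding transcript, and a gene was called bound when a summit lay in it. Summits were assigned to 7 annotation classes in a fixed order of priority, promoter first. Shares were compared with 10000 random placements on the same chromosomes. Bound genes of 27 gene lists were compared with all other protein-coding genes by Fisher's exact test, and summits near genes of 8 non-coding kinds, within 200 bp, by random placement. Chromosomes were compared by exact binomial tests. For 25 sequences, exact McNemar tests set the 200 bp around the summit against a window centred 1000 bp upstream on the plus strand. This flank was used whatever the strand of the gene, so for minus-strand genes it lies on the downstream side. GC content was compared with the same flank by a sign-flip permutation test with 100000 draws. All of these tests were two-sided except the replicate overlap, and p-values were adjusted within each family by the method of Benjamini and Hochberg, with a threshold of 0.05. Regions counted as shared when they overlapped by 1 bp. A replicate's signal for a conservative region was that of the overlapping region with most shared bases in the replicate's own ranked list; 2 regions had none in replicate 1 and 4 none in replicate 2. Columns of the series lists that carry values per replicate name no sample and were not used.

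The lists, sequences, tests and the rule for named genes were fixed before the data were examined. The rule names the genes of the 20 regions with the highest signal, up to 4 bound genes of each list past the threshold, up to 3 of each muscle or attachment list otherwise, *unc-98* and *unc-119*, and up to 3 regions alone in each replicate. Of 265 gene symbols given for the symbol lists, 5 matched no protein-coding gene. Alternatives covered the peak list, each replicate left out, the signal filter, promoter windows, backgrounds, gene assignment, motif windows and controls, and the overlap rule. Shifting summits along their chromosomes keeps their spacing but not their preference for promoters: it gave 247 bound genes on average against 635 observed, so it favours excess over depletion. Under it the 3 depleted lists no longer passed (adjusted permutation p of 0.117 for chemoreceptors, 1 for F-box and MATH-BTB genes and 0.469 for lectins), and the proteasome and spliceosome lists did (0.00630 and 0.0177); because of that bias these changes were not read as evidence either way. Summits redrawn from promoter positions of their own chromosome, a test chosen after seeing the data, gave 531.

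Most tests were run on simulated data; the tests of chromosomes, of strong against weak regions and of promoters on both strands were not. Over 20 lists of 728 uniformly placed regions, the promoter, gene list, non-coding, motif and centre tests made 0 calls, and the class and GC tests 1 each. Uniform regions lack the preference for promoters seen in the conservative list. These calls therefore do not show how often a list with that preference would give false calls. With 30 ribosomal protein genes planted among uniform regions, that list was called in 10 of 10 runs, and 1 call of another list was made that had not been planted. The bound number of chemoreceptor genes in these runs averaged 0.523 of that expected by Fisher's exact test, which takes no account of chromosome or number of 5′ ends. A planted motif was found in 203 windows of 202 expected, a planted overlap of 50% was recovered as 50.2%, and a planted correlation of 0.7 as 0.702. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.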

Results

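The data describe where a GFP-tagged form of UNC-98 was found on the genome of young *Caenorhabditis elegans* larvae. UNC-98 is a C2H2 zinc finger protein of muscle attachment structures that is also seen in nuclei. The strain, OP85, carries a transgene with *unc-98* joined to GFP and epitope tags, together with an *unc-119* rescue gene. Chromatin from whole starved L1 larvae, 6 hours old per the labels, was precipitated with an anti-GFP antibody and sequenced (ChIP-seq) in 2 biological replicates, which form 1 group. The deposited lists hold regions with a signal value and an irreproducible discovery rate (IDR). In the list between replicates this is the expected share of regions that do not recur between them. The IDR of a list from 1 replicate cannot rest on agreement between the 2. Its basis, and that of the second series list, is not stated here. The deposited lists hold no read counts, so the depth of each sample is unknown. The deposited lists were derived with a control file, but no untagged strain was analysed here, so regions that any tagged or untagged strain would give cannot be told apart.

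The first question was how far the replicates shared their regions. The replicate 1 list held 577 regions past the threshold and the replicate 2 list held 394, a 1.46-fold difference. The regions that replicate 1 shared with replicate 2 numbered 298, or 51.6% of its list (95% Wilson interval 47.6 to 55.7%) and 75.6% of the replicate 2 list (71.2 to 79.6%). Random placement of the same regions gave 1.31 shared regions on average and at most 8 (one-sided permutation p = 0.0001, the smallest that the placements can give). The ribosomal protein gene *rpl-35* (III, 7854615 to 7854735, signal 188), the Integrator subunit gene *ints-4* (I, 13663239 to 13663514, 185) and the promoter shared by *iff-2* and F54C9.14 (II, 8561415 to 8561483, 150.2) had the highest signal among the 279 regions of the replicate 1 list alone. Among the 96 of the replicate 2 list alone, the highest were a region in a non-coding gene near Y50D4C.12 (V, 979788 to 980063, 85.0), an intergenic one near *mdl-1* (X, 6741115 to 6741390, 84.0) and an intronic one near *ufbp-1* (III, 8441392 to 8441667, 82.4). Of the regions alone in 1 list, 264 of 279 and 89 of 96 overlapped some candidate region of the other replicate's ranked list. The ranked lists cover 27.8% and 28.7% of the genome, so an overlap alone is weak evidence. The median signal of these candidates was 33.8 in replicate 2 and 29.3 in replicate 1, where each ranked list had a median of 12.7. In replicate 2, *ints-4* had 101.8 and *rpl-35* 63.7. The conservative list held 175 of the 279 and 49 of the 96, so many of these regions were below the threshold in the other replicate rather than absent from it.

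The conservative list of the series, which rests on agreement between both replicates, held 728 regions with a median width of 316 bp. Across the 722 of these with a value in each replicate, the signals of replicate 1 and replicate 2 correlated with Spearman's rho = 0.642 and Pearson's r = 0.742 on the log2 scale (permutation p = 1e-05 for each, two-sided, the smallest that 100000 permutations can give). This is a correlation across regions, which are not independent replicates, in a list already chosen by agreement between the replicates. Over the 74083 ranked regions with a value in each replicate, of 131481, rho was 0.162.

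**Figure D1:**
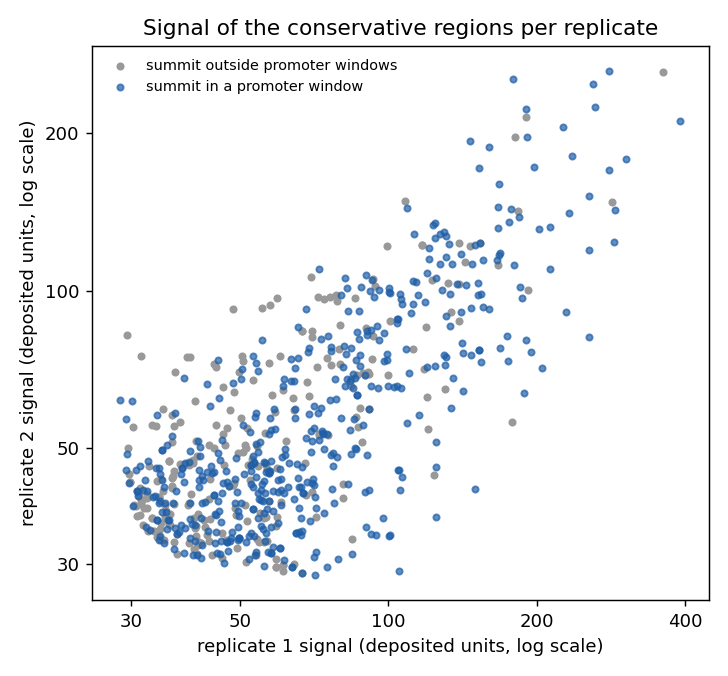
Signal of each region of the conservative list in replicate 1 (x axis) and replicate 2 (y axis), in the deposited units on log axes; 1 point is 1 region, blue where the summit lay in a promoter window and grey elsewhere. The 722 regions with both values run along a common trend with rho = 0.642.

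UNC-98::GFP regions lay mainly at the promoters of protein-coding genes. Of the 728 summits, 478 (65.7%, 95% Wilson interval 62.1 to 69.0%) fell between 1000 bp upstream and 500 bp downstream of an annotated 5′ end, 2.07 times the 31.7% of random placements (two-sided permutation p = 0.0002, the smallest that the placements can give). These promoters belonged to 635 genes, 3.18% of the 19973 protein-coding genes. The summits in promoters had a median offset of -182.5 bp from the nearest 5′ end, and 421 of 478 (88.1%) were upstream of it. The window itself reaches farther upstream than downstream, and no upstream share was computed for random promoter positions. Coding sequence held 9 summits (1.24% against 16.7% expected), introns 92 (0.503 times the 25.1% expected), 3′ UTRs 3 (0.412% against 2.27%) and intergenic sequence 16.9% against 20.8%. Each of these 4 shares was below that of random placements (adjusted permutation p of 0.00035 for the first 3 and 0.0148 for intergenic sequence). Because the classes exclude each other, with promoters first, the excess in promoters by itself lowers the other shares. The tests did not allow for this, so a low share alone does not show that summits avoid a class. Non-coding genes held 22 summits and 5′ UTRs outside promoter windows 1, and neither share passed the threshold. Intergenic sequence lost its difference in the replicate 2 list alone (0.867 of the expected number, adjusted permutation p = 0.275). It reached 1.10 times the expected number with the regions left out of the conservative list restored.

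**Figure D2:**
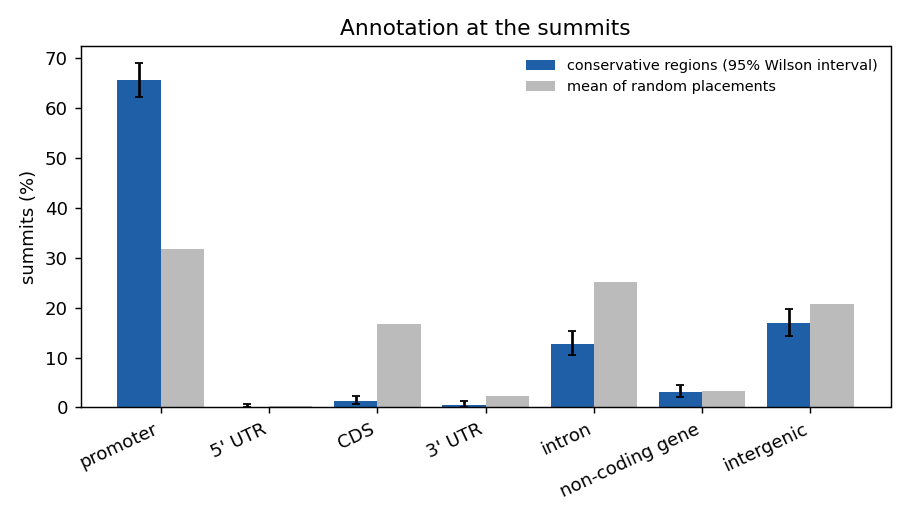
Share of the 728 conservative summits in each annotation class (blue bars, with 95% Wilson intervals) beside the mean share of 10000 random placements (grey bars), in percent. Promoters hold 65.7% of summits against 31.7% at random, and coding sequence 1.24% against 16.7%.

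Of the 20 regions with the highest signal, most lay in promoters and the others were intergenic or in introns. The highest signal, 633, was intergenic, 2611 bp from the nearest 5′ end, that of F58D12.3 (V, 14055111 to 14055341; 360.3 in replicate 1 and 262 in replicate 2). Next came the promoter of *mog-4*, a splicing-related helicase gene (II, 14561754 to 14561966, signal 594), a promoter region of C07H6.2, *cux-7* and *lig-4*, the DNA ligase IV gene (III, 7520750 to 7520953, 543), and that of F56G4.6 and *wbp-4* (I, 11374361 to 11374562, 514). The promoters of K01G5.10 and *tasp-1* (476), *cnk-1* (443), C34C12.9 (440.1), the Hsp70 family genes F44E5.4 and F44E5.5 (439), the ubiquitin ligase gene *eel-1* (433) and Y56A3A.7 (426) followed. K08F11.1 had a region at its promoter (IV, 4725521 to 4725694, 439) and was the nearest gene to an intergenic one (IV, 4727945 to 4728129, 441). The nuclear pore gene *npp-6* and the centrosome gene *spd-5* shared a region (I, 5176295 to 5176491, 426), as did the spliceosomal gene *snr-1* and *snx-13* (IV, 17087476 to 17087635, 417). The remainder of the 20 highest were at *rpl-3* (422), F29B9.11 and the histone demethylase gene *jmjd-1.2* (403), *rpl-20* and Y17G9B.5 (382), K10D2.5, *emb-1* and the splicing gene *prp-19* (381), and in introns of *hmt-1*, an ABC transporter gene (III, 11091711 to 11091915, 400.1), and W05H12.1 (I, 13421108 to 13421295, 381). Above the median signal, 265 of 364 regions (72.8%) had their summit in a promoter, against 213 of 364 (58.5%) below it (odds ratio 1.90, Fisher's exact test, two-sided, p = 6.59e-05).

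Ribosomal protein, translation factor and heat shock genes were bound far more often than other genes. Aminoacyl-tRNA synthetases, also part of protein synthesis, did not pass the threshold (2 of 32, odds ratio 2.03, adjusted p = 0.522, Fisher's exact test). Only 1.02 bound genes were expected in that list, so its count cannot decide whether these genes differ from the others. Regions were present at 19 of 81 cytosolic ribosomal protein genes (odds ratio 9.59, adjusted p = 8.71e-11, Fisher's exact test), 11 of 43 translation factor genes (odds ratio 10.6, adjusted p = 4.73e-07, Fisher's exact test) and 11 of 30 genes of heat shock and proteostasis (odds ratio 17.9, adjusted p = 8.73e-09, Fisher's exact test). Over the alternative lists, windows and gene assignments and with GC content pooled, the odds ratio ranged from 5.80 to 19.1 for ribosomal protein genes. It ranged from 9.19 to 22.2 for heat shock and proteostasis, and was 4.14 or more for translation factors. The lowest for heat shock came with each region given to its nearest gene, which gave 5.82 for ribosomal protein genes. In that setting 11 of 81 ribosomal protein, 6 of 30 heat shock and 8 of 43 translation factor genes were bound. By promoter windows, 184 of the 478 promoter regions (38.5%) counted for several genes. Among ribosomal protein genes the signal was highest at *rpl-3* (III, 3867470 to 3867656; 288 and 124 in replicates 1 and 2), *rpl-20* (IV, 4749998 to 4750152; 233 and 141), *rps-24* (IV, 385495 to 385651; 176 and 135) and *rpl-15* (IV, 654860 to 654998; 229 and 90.9). The leading chaperone genes were *hsp-90* (V, 14685677 to 14685839; 197 and 172; inside the gene, 385 bp upstream of an internal 5′ end), the mitochondrial chaperonin gene *hsp-60* (III, 1619106 to 1619202; 187 and 96.7), the co-chaperone gene *bag-1* (I, 6564585 to 6564712, signal 241) and *cct-8*, of the cytosolic chaperonin (IV, 1094221 to 1094536; 131 and 89.4). For translation factors they were *eif-3.B* (II, 14794998 to 14795313, signal 229), *iff-2* (II, 8561287 to 8561602; 150.2 and 41.7), *eef-1G* (V, 10965598 to 10965913; 91.2 and 59.5) and *eif-3.E* (I, 10642331 to 10642646, signal 143). Neither *iff-2* nor *eif-3.E* was bound in the replicate 2 list, and in that list alone the translation factor list no longer passed (odds ratio 4.14, adjusted p = 0.160, Fisher's exact test).

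Mitochondrial respiration genes were bound at 7 of 70 (odds ratio 3.41, adjusted p = 0.0227, Fisher's exact test), with the highest signal at the cytochrome oxidase genes *cox-5A* (III, 12905148 to 12905242, 256) and *cox-5B* (I, 9788537 to 9788852, 127) and the ATP synthase genes *atp-1* (I, 12652214 to 12652293, 224) and *atp-5* (V, 11123974 to 11124289, 103). This call ended in the replicate 2 list alone (odds ratio 2.47, adjusted p = 0.441, Fisher's exact test). It also ended among the regions above the median signal (odds ratio 2.29), at an IDR of 0.001 (2.00), with each region given to its nearest gene (1.63) and pooled over classes of promoter GC content (2.71, adjusted p = 0.0861; a Mantel-Haenszel test in place of Fisher's). The proteasome genes *pas-1*, *rpn-3*, *rpn-11* and *rpt-4* were bound, 4 of 33 (adjusted p = 0.0598, Fisher's exact test). So were the spliceosome and RNA-binding genes *snr-1*, *snr-4*, *prp-19*, *hrpu-1* and *hrpu-2*, 5 of 55 (adjusted p = 0.0814, Fisher's exact test). Neither list passed the threshold in the conservative list. Spliceosome genes passed in the second series list (7 of 55, odds ratio 4.18, adjusted p = 0.00750, Fisher's exact test). Proteasome genes passed in the replicate 1 list (odds ratio 4.64, adjusted p = 0.0399, Fisher's exact test) and with windows from 2000 bp upstream (4.15, adjusted p = 0.0327, Fisher's exact test). In the replicate 2 list 0 proteasome genes were bound. The *rpn-3* region (III, 8446993 to 8447308) was also that of *hsp-110* and counted in the heat shock list too.

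Muscle genes, the tissue with which UNC-98 is best connected, gave a mixed picture. Body wall muscle contraction genes were bound at 6 of 31 (odds ratio 7.37, adjusted p = 0.00203, Fisher's exact test), all with signals below the median of the list. They included the myosin heavy chain gene *unc-54* (I, 14863487 to 14863802, signal 98.1; 41.3 and 45.5 in replicates 1 and 2), the calcium pump gene *sca-1* (III, 10816976 to 10817291, 87.4), the troponin T gene *mup-2* (X, 6410437 to 6410752, 80.8) and the calponin-like gene *cpn-3* (I, 3987163 to 3987478, 79.9). *unc-54* was bound in neither replicate's own list, *sca-1* not in that of replicate 1, and *mup-2* and *cpn-3* not in that of replicate 2. None of the 31 was bound among the regions above the median signal, and in the replicate 2 list alone the odds ratio was 1.83 (adjusted p = 0.848, Fisher's exact test). At an IDR of 0.001 the odds ratio of the contraction list was 0. This was fixed, because none of its regions in the conservative list reached that IDR. In the replicate 1 list alone the odds ratio was 4.98. Every other setting that used both replicates kept the call. The odds ratio was 6.88 in the second series list and 12.8 with each region given to its nearest gene. Pooled over classes of promoter GC content it was 4.58. Against promoter positions of the same chromosome the bound number was 6.76 times that expected. Of 25 genes of M-line and dense body attachment, the list that holds *unc-98* itself, 1 was bound, the giant muscle kinase gene *unc-22* (IV, 12010435 to 12010750, 93.2; adjusted p = 0.856, Fisher's exact test), which was not bound in the replicate 2 list. Of the 12 muscle transcription factor genes and 13 pharyngeal muscle genes, 0 were bound (adjusted p = 1 for each, Fisher's exact test). Only 0.382 and 0.413 were expected in these lists and 0.795 in the attachment list, so these low counts say little.

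Large families of environmental response genes were bound less often than other genes by the planned test. Regions were found at 5 of 1360 chemoreceptor-like names (odds ratio 0.105, adjusted p = 2.04e-12), 3 of 388 F-box and MATH-BTB genes (odds ratio 0.234, adjusted p = 0.0117) and 0 of 237 C-type lectin genes (adjusted p = 0.00475), each by Fisher's exact test. The members were *srh-2* (V, 731357 to 731672, signal 125), *sri-5* (I, 11182394 to 11182709, 121), *srh-89* (V, 7465584 to 7465899, 120.4), *srp-7* (V, 8179196 to 8179511, 92.5), *sre-23*, *fbxb-58* (X, 1627001 to 1627316, 219), *fbxa-90* (V, 16965703 to 16966018, 167) and *fbxb-85* (III, 10848874 to 10849189, 82.1), of which *srp-7* is a serpin gene caught by the name pattern. In simulated lists with no effect on chemoreceptors, their bound number was only 0.523 of what Fisher's exact test expects. A test chosen after seeing the data therefore redrew the summits in promoters from the promoter positions of the same chromosome. Chemoreceptors stayed at 0.203 of the number so expected (adjusted permutation p = 0.00135) and lectins at 0 against 5.35 (adjusted permutation p = 0.0378). F-box and MATH-BTB genes, at 0.310, did not pass (adjusted permutation p = 0.0999). In the replicate 2 list alone, with fewer regions, the F-box odds ratio was 0.139 and that of lectins 0, and neither passed (adjusted p of 0.0771 and 0.109, Fisher's exact test). Neither passed above the median signal (0.171 and 0.0871) or at an IDR of 0.001 (0.520 and 0.240), also by Fisher's exact test. *fbxb-85* was bound in neither replicate's own list.

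Marker genes of other tissues had no region, but so few were expected that this says little. Of the lists for intestine (25 genes), epidermis (28), neurons (35) and germ line (23), and of those for insulin signalling and starvation response (38), vacuolar ATPase (20), histones (50), homeobox genes (90) and bHLH factors (37), 0 genes had a region, where 0.636 to 2.86 were expected per list and the adjusted p was 0.273 or more (Fisher's exact test). Bound members of the other lists, named after their values were seen, were *ears-2* and *kars-1* of 32 aminoacyl-tRNA synthetases, *ztf-7*, *zip-2*, *zip-4* and *zip-11* of 71 names meant to mark zinc finger factors (the *zip* genes encode bZIP factors), *col-71* and *col-85* of 177 collagens, *nhr-48*, *nhr-141* and *nhr-255* of 269 nuclear hormone receptors, and *ins-39* of 39 insulin-like peptides. None of these 5 lists passed the threshold in the conservative list (adjusted p from 0.128 to 1, Fisher's exact test). Nuclear hormone receptors passed as depleted in the replicate 1 list (odds ratio 0.123, adjusted p = 0.0211, Fisher's exact test) and with windows of 500 bp upstream to 200 bp downstream (0 bound, adjusted p = 0.00906, Fisher's exact test).

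**Figure D3:**
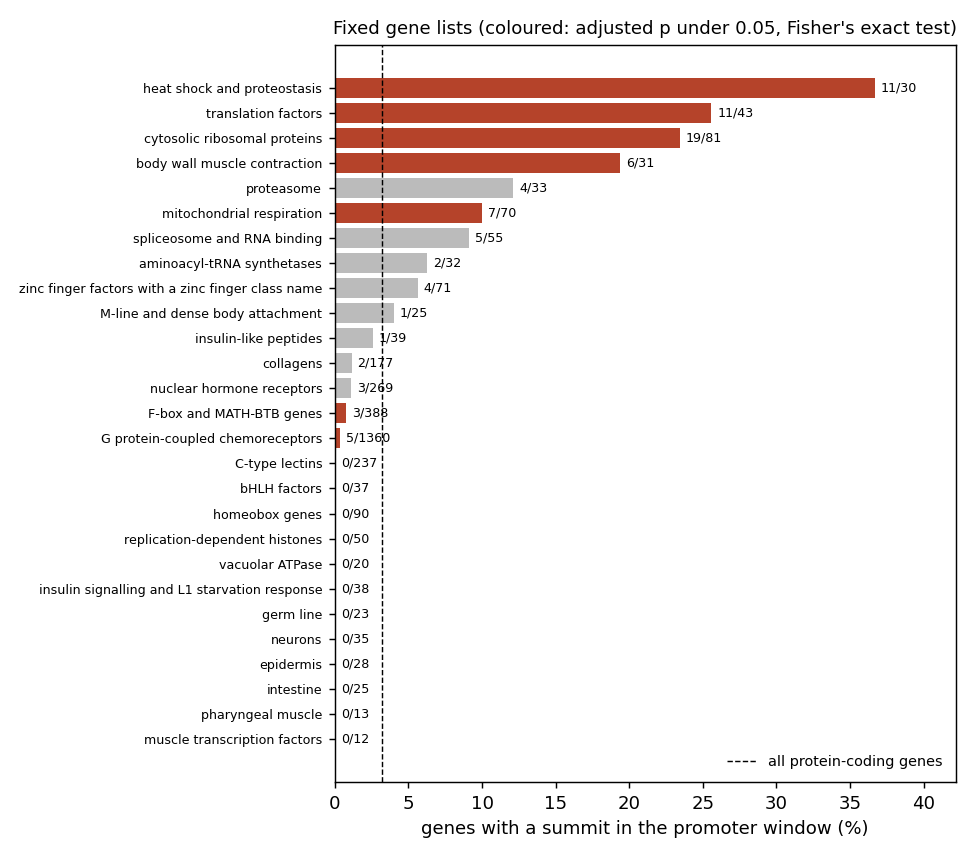
Share of the genes of each of the 27 lists with a conservative summit in the promoter window, in percent, with the bound and total genes at each bar. Coloured bars passed Fisher's exact test after adjustment, as did C-type lectins with a bar of 0; the dashed line is the 3.18% of all protein-coding genes, and heat shock and proteostasis genes lead with 36.7%.

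Genes of small structural RNAs were strongly represented. Within 200 bp of a tRNA gene lay 36 summits, 19.8 times the random number, within that distance of a small nucleolar RNA gene 23 (16.3 times) and of a small nuclear RNA gene 9 (19.3 times), each with adjusted permutation p = 0.0004. Without a replicate the tRNA excess ranged from 11.4 to 14.1 times. piRNA genes had 4 nearby summits (0.170 of the random number, 0.0737 to 0.282 without a replicate; adjusted permutation p = 0.0004) and pseudogenes 11 (0.405, adjusted permutation p = 0.00128). Long non-coding RNA genes had 8 (2.39 times, adjusted permutation p = 0.0568), microRNA genes 1 and ribosomal RNA genes 0, none past the threshold. With the summit required inside the gene, small nucleolar RNA, small nuclear RNA and piRNA genes no longer passed (2.73, 9.28 and 0 times, adjusted permutation p of 0.814, 0.542 and 0.612). Pseudogenes no longer passed in the replicate 2 list alone, though the value was close to that of the conservative list (0.465, adjusted permutation p = 0.0518). They also did not pass above the median signal (0.583), at an IDR of 0.001 (0.571) or within 500 bp (0.691). Random placement does not keep the preference of summits for coding promoters, and no control with promoter positions was run for the non-coding kinds. The low numbers at piRNA genes and pseudogenes are therefore not separated from that preference.

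Neither gene carried by the transgene had a region in the conservative list. At *unc-98* (X, 7570374 to 7573619, minus strand) the promoter windows held 0 candidate regions of any rank in the list between replicates and in each replicate's ranked list. At *unc-119* (III, 10902641 to 10908935, plus strand) they held 6 candidates between replicates, the highest with a −log10 IDR of 0.325, below the threshold of 2.

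**Figure D4:**
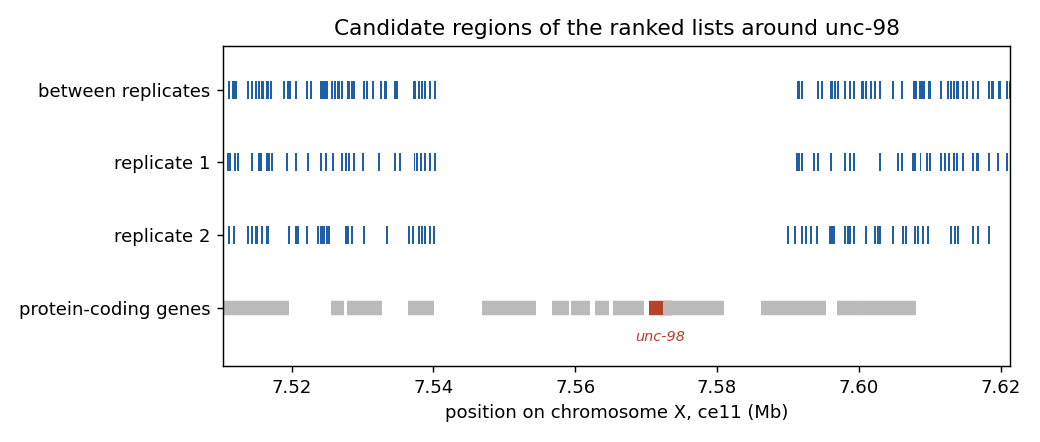
Candidate regions of the ranked lists (blue, 1 row per list) and protein-coding genes (grey, *unc-98* in red) along chromosome X in ce11, in Mb. No candidate lies between 7540357 and 7591339 in the list between replicates, a stretch of 51.0 kb that holds *unc-98*.

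The regions were spread unevenly over the chromosomes. Chromosome III held 155 (1.55 times what its length gives, adjusted p = 1.51e-07, exact binomial test) and chromosome I 135 (1.23 times, adjusted p = 0.0142, exact binomial test). Chromosome V held 106 (0.698 times, adjusted p = 5.14e-05, exact binomial test) and X held 91 (0.707 times, adjusted p = 0.000353, exact binomial test), while II (1.05 times) and IV (0.976 times) did not pass. Against the number of protein-coding 5′ ends per chromosome, X was at 0.897 of the expected number and no longer passed (adjusted p = 0.427, exact binomial test), and chromosome I did not pass in either replicate's list alone (1.16 times for replicate 1 and 1.05 for replicate 2). Chromosome I also did not pass in the second series list (1.15), above the median signal (1.17) or at an IDR of 0.001 (1.11), nor did V at that IDR (0.749, adjusted p = 0.0629, exact binomial test). The central 33.3% of the autosomes' lengths held 30.5% of autosomal summits (194 of 637, exact binomial p = 0.130). In the replicate 2 list alone this share was 0.825 of the expected one (exact binomial p = 0.0230), and against protein-coding 5′ ends it was 0.782 (exact binomial p = 9.11e-06).

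Summits were rich in GC and in GAGA repeats. GC content over 200 bp was 43.4 ± 7.58% (SD, n = 728 regions) at summits. It was 36.8 ± 7.47% in flank windows 1000 bp upstream on the plus strand, whatever the strand of the gene. The difference was 6.61 points (SE 0.387; sign-flip permutation p = 1e-05, the smallest the permutations can give). Of 25 sequences fixed beforehand, 6 were more frequent at summits than in the flank and 5 less frequent. GAGAGA occurred at 32.1% of summits and 11.1% of flanks (adjusted p = 4.75e-22, exact McNemar test), the E2F-type site at 15.7% and 6.32% (adjusted p = 4.10e-08, exact McNemar test) and the GC box at 10.4% and 3.98% (adjusted p = 2.65e-05, exact McNemar test). The B box of tRNA genes occurred at 3.57% and 0.412% (adjusted p = 6.61e-05), the E-box CACGTG at 7.55% and 4.40%, and the M1-like sequence at 3.43% and 1.37% (adjusted p = 0.0379 for both, exact McNemar tests). GATA sites (25.5% and 34.3%), homeodomain sites (5.08% and 9.75%), T runs (12.5% and 21.3%), the Inr-like sequence (14.6% and 20.2%) and TTTTCAG (13.5% and 22.5%) were less frequent at summits (adjusted p from 4.28e-05 to 0.0113, exact McNemar tests). Against promoter positions of matched GC content, a control chosen after seeing the data, GAGAGA kept its excess (32.1% against 15.9%, adjusted p = 1.22e-11, Fisher's exact test). Under that control the calls of the GC box (adjusted p = 0.166), CACGTG (0.367), homeodomain sites (0.676), T runs (0.367) and TTTTCAG (0.288) ended by Fisher's exact test, while the heat shock element passed (3.57% against 0.824%, adjusted p = 0.00389, Fisher's exact test). In the replicate 2 list alone, CACGTG, the GC box, the B box, the M1-like, homeodomain and Inr-like sequences did not pass (adjusted p from 0.0530 to 0.393, exact McNemar tests). Neither did CACGTG, homeodomain and Inr-like sequences in that of replicate 1 (0.184 to 0.450 by the same exact tests). Only GAGAGA and the E2F-type site passed in every alternative. CACGTG passed in 2 of 12, the second series list and random promoter positions as control. Within 200 bp of the summit the calls of GATA sites (-5.08 points, adjusted p = 0.129), homeodomain sites (-1.51, 0.587), T runs (0.0503) and the M1-like sequence (0.0912) also ended by exact McNemar tests. At an IDR of 0.001 those of GATA sites (0.0917), homeodomain sites (0.952), T runs (0.149), the B box (0.195), the Inr-like sequence (0.102) and TTTTCAG (0.0634) ended by the same exact tests. The B box (0.0502) and Inr-like sequence (0.171) ended within 50 bp, the B box (0.244) and homeodomain sites (0.190) above the median signal, and the M1-like sequence (0.0506) in the second series list, by exact tests. In points, the CACGTG difference was 1.56 in the replicate 1 list and 3.30 in that of replicate 2, against 3.16 in the conservative list. The M1-like difference was 2.43 and 2.79, against 2.06. In the replicate 2 list the GC box (4.06 against 6.46), the B box (1.52 against 3.16), homeodomain sites (-2.54 against -4.67) and the Inr-like sequence (-3.55 against -5.63) all differed less.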

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

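The test of extra transgene copies at *unc-98* was chosen only after the result was seen; the other tests were written down after the patterns were known but before their own values were seen.

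In data outside the report's comparisons, 66 regions of the ranked list between replicates passed the IDR threshold and were left out of the conservative list. They included the 3 with the highest signal of all, near Y7A5A.7 (X, 15810939 to 15811179, signal 1767), near R57.2 (X, 293334 to 293509, 1114) and near *lgc-26* (V, 265038 to 265353, 773), where the highest kept was 633. Only 2 of the 66 (3.03%) had their summit in a promoter, against 65.7% of the kept regions (Fisher's exact test, p = 2.11e-25). Of the 66, 0% lay within 25 kb of *unc-98* or *unc-119*. This cannot decide on extra copies of the transgene, since the ranked list held no candidate around *unc-98* (X, 7540357 to 7591339). Repeated sequence may account for the left-out regions. The median share of 31-base words present more than once in the reference was 90.2%, against 0% in the kept regions. Repeats are not the whole rule, since 62 of the 728 kept regions were also over 50% repeated, and no biological explanation was tested with 1 group.

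The excess of ribosomal protein, translation factor and chaperone promoters was weighed against properties of these promoters. GC content is argued against as the whole cause, since the odds ratio of the 3 lists together, pooled over 10 classes of promoter GC content, was 7.96 (95% interval 5.49 to 11.6). Gene density stays open. The 41 bound genes of the 3 lists were 20.4 times the mean over chromosome shifts. The shifts lose the preference for promoters, with all bound genes at 635 against 247. Against promoter positions of the same chromosome, a test chosen after seeing the data, ribosomal protein, translation factor and heat shock genes were at 7.94, 7.70 and 12.7 times. All bound genes were 635 against 531 there, so promoter preference alone does not give the excess. Those draws do not keep local gene density. Whether any tagged protein or an untagged strain gives the same promoters stays open, as no such sample was analysed here, and no biological explanation was tested.

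The *unc-98* locus lay in a stretch of 51.0 kb without a candidate region (X, 7540357 to 7591339), against a median of 0.387 kb between candidates. Repeated sequence is argued against there, with 0.233% of repeated 31-base words, unlike the chromosome V stretches among the 5 longest, where the share was 99.8% and repeats may account for the gap. Extra copies of the transgene insert, which could raise the control as much as the precipitate, stay open: the stretch ranked 5 by length in each replicate's list. That test cannot decide, because the stretch itself prompted the explanation, and no biological explanation was tested.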

How the results depend on the processing

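Alternatives with an IDR of 0.001, overlapping regions reduced to the highest, left-out regions restored, promoter positions redrawn, or GC content matched or pooled were chosen after seeing the data; the planned IDR of 0.01 moves nothing and was not run. Promoter share (1.59 to 3.32 times random over 12 alternatives), strong against weak regions, GC content, replicate overlap and signal correlation kept their direction and their side of the threshold in every alternative run. Without a replicate, promoter share ranged from 2.03 to 2.23 times, lists past the threshold from 3 to 10 (main 8), sequences from 5 to 8 (main 11), X from 0.646 to 0.657 and the autosome centre from 0.825 to 0.929. Lists past the threshold numbered 4 above the median signal and 4 at an IDR of 0.001, where fewer regions enter. Body wall muscle contraction had odds ratios of 0 and 0 there. Both were fixed, because these settings only take regions from the conservative list. All contraction gene regions of that list lay below the median signal, and none had an IDR of 0.001 or less. Sequences past the threshold numbered 4 at that IDR, 6 within 200 bp and 7 against promoters of matched GC content, where homeodomain sites (0.69 points) and T runs (2.06 points) turned from fewer to more frequent without passing. Non-coding kinds numbered 2 with the summit inside the gene (main 5). Against 5′ ends X was at 0.897 and II at 0.960. The autosome centre passed in the second series list (0.886), at an IDR of 0.001 (0.784) and against 5′ ends (0.782). Intergenic sequence reached 1.10 with the left-out regions restored, and chromosome IV, without a replicate, ranged from 0.924 to 1.05 and was at 1.04 at an IDR of 0.001. The cause was not tested. No paired analysis was possible because both samples belong to 1 group. Of 53 named genes with a promoter region, 43 remained bound in the replicate 2 list and 50 in the replicate 1 list. Unknown depth limits what absence from a list shows.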

Other observations

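Bound promoter regions often fell in the windows of genes on both strands. Of the 478 promoter regions, 167 (34.9%, 95% Wilson interval 30.8 to 39.3%) lay in the promoter windows of protein-coding genes on both strands, against 9.19% of 10000 random promoter positions (odds ratio 5.31, Fisher's exact test, p = 3.23e-50). Among the 20 regions with the highest signal these windows included *npp-6* with *spd-5* and *snr-1* with *snx-13*. The count does not require that the genes face apart, and the *npp-6* summit lay inside *spd-5*. The comparison was chosen after the data were examined, and random positions do not keep the summits' distance from the 5′ end.

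The conservative list held regions that the thresholded lists of single replicates did not. Of its 728 regions, 302 (41.5%) overlapped a region of both replicates' lists and 199 (27.3%) overlapped none. The list also held 27 pairs of overlapping regions, and 701 regions remained when only the highest signal of each overlapping group was kept.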
